A study of Mus musculus with 18 samples.

How the data were processed

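The samples were 18 RNA sequencing libraries of mouse lung neutrophils in 6 groups of 3, sorted as live CD45+ CD11b+ Ly6G+ cells and by CD101. The deposited values are raw read counts per gene. Per the submitters' processing notes, the authors made these counts with STAR 2.5.1a, Subread and featureCounts 1.4.6-p5 from total RNA libraries of the SMARTer kit. The genome build, the annotation release and the strand setting are not given in the sources used here, so reads of overlapping genes on opposite strands cannot be told apart and no coordinates are given. Reads shared between close paralogs, such as Tgtp1, Chil3 and the Ear genes, leave the source of those counts uncertain.

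The table held 40757 lines, of which 276 repeated a gene ID with identical counts and were counted once, giving 40481 gene IDs. Of these 40254 had a name in the reference used here, and 15196 newer reference IDs, all above the highest ID in the table, were not analysed here. No sample column was left out. Libraries held 33.7 to 52.6 M counts in WT naive, 53.4 to 63.8 M in CGD naive, 56.3 to 59.0 M in WT zymosan CD101pos, 60.1 to 67.9 M in CGD zymosan CD101pos, 51.9 to 57.1 M in WT zymosan CD101neg and 54.5 to 64.0 M in CGD zymosan CD101neg cells. The filter filterByExpr by group kept 16575 genes, 13807 of them protein-coding, with at least 99.967% of each library's counts.

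Groups were compared with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test (robust) in 1 fit of all 18 libraries with TMM factors and 12 residual degrees of freedom. The common biological coefficient of variation was 33.0%. Genes passed at an adjusted p under 0.05 (Benjamini and Hochberg). There were 7 pairwise comparisons and 2 interactions. The interaction of genotype with subset is the CD101neg against CD101pos difference of CGD minus that of WT after zymosan, and the interaction of genotype with zymosan is the zymosan against naive difference of CGD CD101pos cells minus that of WT. CPM use the TMM factors. The SE of a log2 fold change is its size divided by the square root of the F statistic.

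Gene lists were tested with camera of limma 3.58.1 at the preset correlation of 0.01 between genes, adjusted over the 33 lists of a comparison. Of the lists, 20 hold genes of a process, 12 hold markers of other cell types and 1 holds sex-linked genes. They name primary granule, secondary and tertiary granule, mature neutrophil, cell cycle, NADPH oxidase, cytokine and chemokine, IL-1 and inflammasome, G-CSF and granulopoiesis, NF-kB target, interferon-stimulated, antioxidant and NRF2, glycolysis and hypoxia, nuclear oxidative phosphorylation, mitochondrially encoded, ribosomal protein, leukotriene and prostanoid, microbial recognition, unfolded protein response, immediate early, and antigen presentation genes. The markers are of alveolar macrophages, monocytes and interstitial macrophages, eosinophils, basophils and mast cells, dendritic cells, T and NK cells, B cells, epithelial cells, endothelial cells, fibroblasts, platelets and erythroid cells.

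Named genes follow a fixed rule. Each has an adjusted p under 0.05, a mean of at least 10 CPM in the higher group and, in pairwise comparisons, all 3 libraries of one group above all 3 of the other, and predicted gene models are left out. The 10 largest changes in each direction were taken, with up to 4 members of each list that had the lowest p (2 where none passed), Cybb, and the NADPH oxidase and sex-linked lists. List members did not need the CPM minimum or the separation.

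Alternatives were RLE size factors, DESeq2 1.42.0, no low-count filter, only the groups compared in the fit (4 residual degrees of freedom for 2 groups), the replicate number as a block, each library left out in turn and, for lists, camera with an estimated correlation and fry. Scaling by library size only was chosen after seeing the data, when the TMM factors were seen to differ between groups. The method was tested on simulated data with 16099 genes. For the genotype comparison of CD101neg cells it recovered 24% of 100 genes changed 2-fold and 79% of those changed 4-fold, for the CGD subsets 31% and 76%, and for the interaction with subset 5% and 55%. Calls among unchanged genes made up 3.51%, 6.84% and 4.69% of all calls, the second above the 5% aimed at, and there camera also called 1 list that had not been shifted.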

Results

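RNA sequencing counts were compared between wild-type (WT) mice and mice with a disrupted Cybb, both on the C57BL/6 background. Cybb encodes gp91phox, the catalytic subunit of the phagocyte NADPH oxidase, and its loss causes chronic granulomatous disease (CGD), in which neutrophils cannot make the oxidative burst. The cells were live CD45+ CD11b+ Ly6G+ neutrophils sorted from digested lungs and split by CD101, a surface protein that neutrophils gain as they mature, so that the labels call CD101-negative (CD101neg) cells immature and CD101-positive (CD101pos) cells mature. Zymosan, a preparation of yeast cell wall, had been given into the nose at 20 µg 24 hours before the zymosan groups were collected. There were 6 groups of 3 libraries, namely naive CD101pos, zymosan CD101pos and zymosan CD101neg cells of each genotype. No naive CD101neg group was present among these samples. Zymosan-treated mice were female and 13 weeks old and naive mice were male and 12 weeks old, so every comparison of zymosan with naive cells is also one of sex and age. Nothing in the sources used here states that the replicates of a group are separate animals, so the p-values measure the spread between these samples.

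Between 33.7 and 67.9 M reads per library lay in genes, with the fewest in WT naive libraries (33.7 to 52.6 M). Between 19304 and 20671 genes had a count in a library, and 16575 genes, 13807 of them protein-coding, had enough reads to be tested. Correlations between replicates of a group, across genes, lay between 0.958 and 0.981. The first principal component held 31.3% of the variance and put naive libraries (41.3 to 79.2) apart from WT zymosan (-15.5 to 14.2), CGD zymosan CD101pos (-46.6 to -39.7) and CGD zymosan CD101neg libraries (-85.5 to -74.1). The TMM scaling factors were lowest in CGD CD101neg libraries (0.702 to 0.809) and highest in WT naive libraries (1.16 to 1.24). Reads in mitochondrially encoded genes made up between 0.316% and 0.764% of a library, and the 10 most abundant genes between 17.8% and 26.9%. Levels are given as CPM (reads per M reads), mean ± SD of 3 libraries, and log2 fold changes with their standard error (SE).

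**Figure D1:**
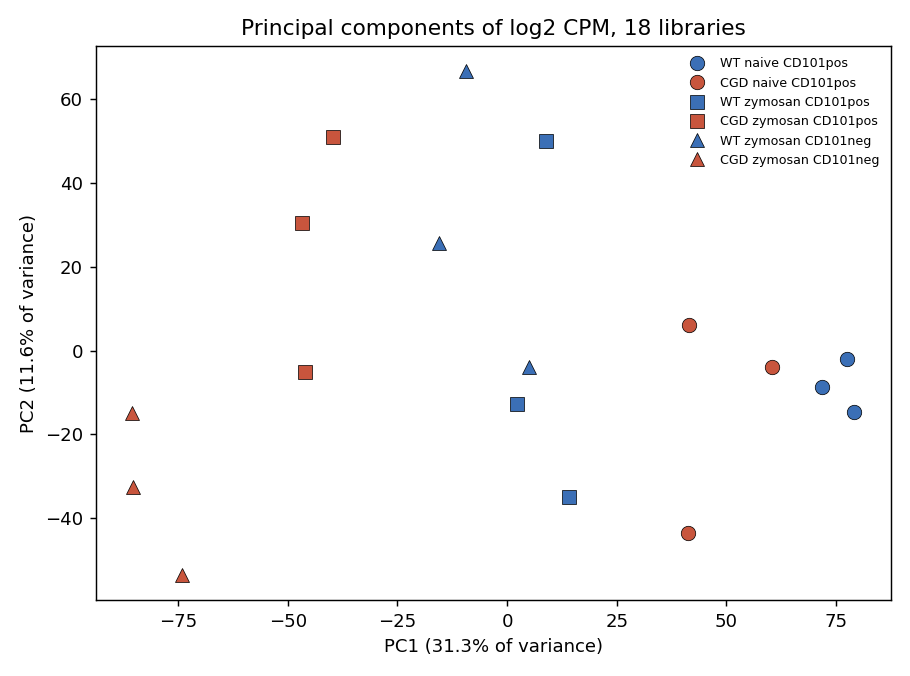
Each point is 1 of the 18 libraries on the first (x axis, 31.3% of variance) and second (y axis, 11.6% of variance) principal components of log2 CPM, coloured by genotype and shaped by sort and treatment. All 3 CGD CD101neg libraries lie between -85.5 and -74.1 on the first component and all naive libraries between 41.3 and 79.2.

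Cybb (ENSMUSG00000015340) carried far fewer reads in every CGD library than in any WT library of the same sort, as the genotype labels give. It stood at 17.1% of the WT level in zymosan CD101neg cells (45.1 ± 4.66 against 263 ± 10.1 CPM), 18.9% in zymosan CD101pos cells (32.6 ± 2.70 against 173 ± 41.5 CPM) and 21.3% in naive cells (54.7 ± 4.39 against 257 ± 22.4 CPM). The log2 fold changes were -2.55 ± 0.19, -2.40 ± 0.19 and -2.23 ± 0.19 (adjusted p = 8.15e-07, 9.8e-07 and 5.89e-06). Reads remaining at a disrupted gene do not show whether protein was made. Xist, the RNA that silences an X chromosome, was at most 0.0269 CPM on average in naive groups and at least 8.45 CPM in zymosan groups. The Y-linked Ddx3y was at 84.9 and 104 CPM in WT and CGD naive cells and at most 0.21 CPM in zymosan groups, as the labelled sexes give. Cd101 (ENSMUSG00000086564) was at 375 ± 60 CPM in WT naive, 301 ± 72.2 in CGD naive, 403 ± 70.3 in WT zymosan CD101pos, 166 ± 16.1 in WT zymosan CD101neg, 105 ± 7.96 in CGD zymosan CD101pos and 61.1 ± 18.4 in CGD zymosan CD101neg cells. All 3 CGD libraries sorted as CD101pos after zymosan lay below all 3 WT libraries sorted as CD101neg, a difference that was not tested.

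**Figure D2:**
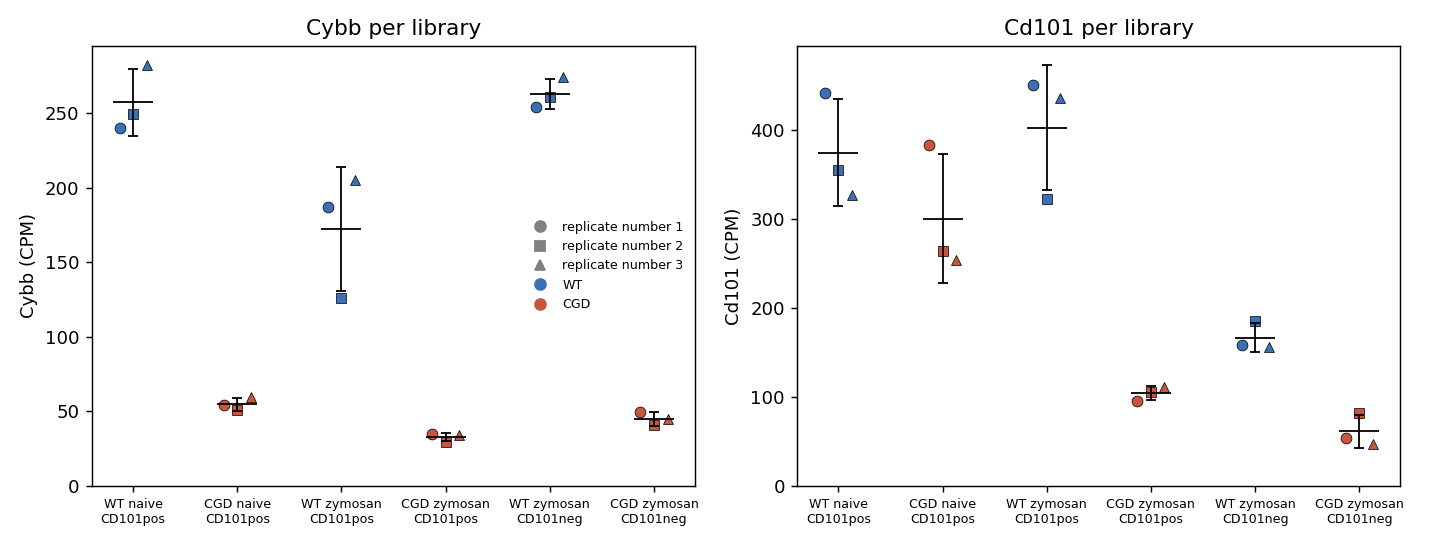
Cybb (left) and Cd101 (right) in CPM (y axes, from 0) for each library of the 6 groups (x axes), with symbols for replicate numbers and colours for genotype. Horizontal lines are group means and bars 1 SD of 3 libraries. The highest CGD library has 59.5 CPM of Cybb and the lowest WT library 126 CPM, and Cd101 is lowest in CGD zymosan CD101neg cells (61.1 CPM).

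**Figure D3:**
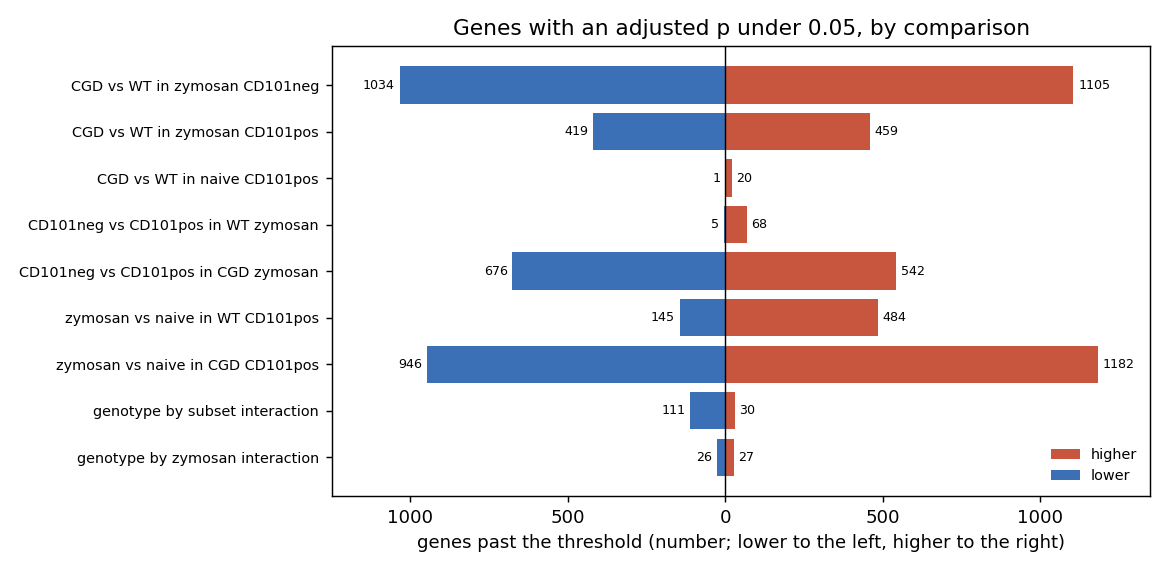
Bars show the number of genes (x axis) with an adjusted p under 0.05 in each of the 9 comparisons (y axis), higher to the right and lower to the left. The CGD against WT difference in zymosan CD101neg cells gives 1105 higher and 1034 lower genes, and the naive one 20 and 1.

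Of the 33 gene lists, fixed with the named-gene rule before the data were examined, 19, 12 and 15 passed camera's test in the genotype comparisons of zymosan CD101neg, zymosan CD101pos and naive cells. The subset comparisons of WT and CGD had 8 and 12, the zymosan comparisons 22 and 14, and the interactions of genotype with subset and with zymosan 17 and 4. With the correlation between a list's genes estimated from the data, which makes the test stricter here, 2, 0, 0, 1, 2, 8, 5, 2 and 0 of them passed, in the same order. In no comparison did the lists of G-CSF and granulopoiesis genes (lowest adjusted p = 0.149) or of basophil and mast cell (0.282), platelet (0.0528) and erythroid markers (0.485) pass.

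Immature CGD neutrophils from zymosan-treated lungs carried more transcripts of single genes such as Cxcl3, Il12a, Irak3 and Pfkp than WT ones, and fewer of Prdx1 and catalase. Of the 19 lists that passed, IL-1 and inflammasome genes (7 of 17 rose) and B cell markers (7 of 9 fell) did so also with an estimated correlation (adjusted p = 0.0143 for both). The comparison asks what loss of the oxidase changes in CD101neg cells during inflammation, and 2139 of 16575 genes passed, 1105 higher and 1034 lower in CGD. The largest increases were in the interferon-induced GTPase Tgtp1 (log2 fold change 5.26 ± 0.81) and in Cxcl11 (5.09 ± 0.83) and Cxcl9 (4.69 ± 0.83), ligands of the lymphocyte receptor CXCR3. The largest decreases were in the lipoxygenase Alox15 (-6.98 ± 1.13), the immunoglobulin light chain Igkc (-3.70 ± 0.36) and the stress-induced cytokine Gdf15 (-3.64 ± 0.77). Spp1, which encodes osteopontin, was at 8906 ± 3689 against 615 ± 247 CPM (3.86 ± 0.61).

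Among cytokine and chemokine genes, 8 of 30 measured rose, 1 fell and 21 did not pass. The cytokine list had 11 up and 2 down adjusted over the list alone, median 0.83 (camera adjusted p = 2.43e-07, adjusted p = 0.358 with an estimated correlation). Il12a, the p35 subunit of interleukin-12, was at 86.6 ± 10.5 against 8.97 ± 0.64 CPM (3.27 ± 0.28, adjusted p = 1.64e-06). The neutrophil attractant Cxcl3 was at 5396 ± 619 against 569 ± 196 CPM (3.24 ± 0.30), and Csf3, which encodes G-CSF, at 65.4 ± 7.72 against 12.0 ± 4.56 CPM (2.44 ± 0.31). Of 17 IL-1 and inflammasome genes 7 rose and 10 did not pass. The IL-1 list had 8 past adjusted over the list alone, median 0.82 (camera adjusted p = 2.26e-08, adjusted p = 0.0143 with an estimated correlation). They include Irak3, a brake on Toll-like and IL-1 receptor signalling (284 ± 48.3 against 50.8 ± 8.32 CPM, 2.49 ± 0.21), the decoy receptor Il1r2 (1.51 ± 0.32) and Mefv, which encodes pyrin (1.31 ± 0.23). NF-kB target genes rose in 8 of 25, with Nfkb1 at 1.56 ± 0.18 and Cflar at 1.23 ± 0.23. The NF-kB list had 10 past adjusted over the list alone, median 0.92 (camera adjusted p = 5.03e-07, adjusted p = 0.373 with an estimated correlation). Fungal and microbial recognition genes rose in 8 of 22, among them the lipopolysaccharide co-receptor Cd14 (50239 ± 6130.1 against 17211 ± 1843 CPM, 1.55 ± 0.24). The recognition list had 12 up and 1 down adjusted over the list alone, median 0.55 (adjusted p = 9.77e-07, adjusted p = 0.136 with an estimated correlation).

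Interferon-stimulated genes rose in 16 of 37 measured and fell in 0. The interferon list had 24 past adjusted over the list alone, median 1.08 (adjusted p = 6.98e-10, adjusted p = 0.4 with an estimated correlation). The chemokine Cxcl10 was at 866 ± 717 against 44.7 ± 15.8 CPM (4.28 ± 0.60), the GTPase Ifi47 at 511 ± 466 against 28.4 ± 2.44 CPM (4.17 ± 0.57) and the ubiquitin-like Isg15 at 1.81 ± 0.36. They were highest in CGD CD101neg replicate 3, whose mean over the list was 6.90 log2 CPM against 5.00 and 5.51 in the other CGD CD101neg libraries. Without that library 5 of the 16 kept their call and the list median was 0.49. Glycolysis and hypoxia genes rose in 6 of 31 and fell in 1. The glycolysis list had 11 up and 2 down adjusted over the list alone, median 0.59 (adjusted p = 4.34e-05, adjusted p = 0.4 with an estimated correlation). The phosphofructokinase Pfkp went from 50.8 ± 0.82 in WT to 268 ± 68.5 CPM in CGD (2.40 ± 0.20) and the hexokinase Hk1 by 1.24 ± 0.22. Antioxidant and NRF2 genes went both ways, 5 up and 11 down of 25. The NRF2 list had 5 up and 12 down adjusted over the list alone, median -0.53 (adjusted p = 0.00744, adjusted p = 0.4 with an estimated correlation). The peroxiredoxin Prdx1 was at 69.3 ± 4.32 against 418 ± 135 CPM (-2.59 ± 0.25), catalase (Cat) at -1.73 ± 0.22 and the quinone reductase Nqo1 at -2.76 ± 0.42, while the metallothionein Mt2 was higher (2.28 ± 0.30). Ribosomal protein genes fell in 12 of 48, for example Rpl5 (-0.75 ± 0.16). Their list had 22 past adjusted over the list alone, median -0.47 (adjusted p = 6.54e-08, 0.423 with an estimated correlation). Secondary and tertiary granule genes rose in 4 of 19, led by Chil3 (2.56 ± 0.42) and Olfm4 (2.01 ± 0.45), and the list lost its call without WT CD101neg replicate 1 (median 0.43, adjusted p = 0.0845). The granule list had 6 up and 1 down adjusted over the list alone, median 0.86 (adjusted p = 0.00146, adjusted p = 0.515 with an estimated correlation).

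Beside these groups, mitochondrially encoded genes held 0.316% to 0.359% of the reads of CGD and 0.492% to 0.581% of those of WT CD101neg libraries, and the 10 most abundant genes 25.0% to 26.9% and 19.9% to 21.1%. B cell markers fell in 7 of 9. Their list had 1 up and 8 down adjusted over the list alone, median -2.16 (adjusted p = 1.51e-12, 0.0143 with an estimated correlation). Monocyte and interstitial macrophage markers fell in 10 of 14. Their list had 1 up and 11 down adjusted over the list alone, median -1.20 (adjusted p = 6.16e-07, 0.063 with an estimated correlation). Alveolar macrophage markers fell in 7 of 15, a list call lost without WT CD101neg replicate 1 (median -0.53, adjusted p = 0.0503). Their list had 2 up and 7 down adjusted over the list alone, median -0.59 (adjusted p = 0.00843, 0.429 with an estimated correlation). The complement genes C1qa (2.58 ± 0.454 against 11.1 ± 3.87 CPM, -2.10 ± 0.32) and C1qb (-1.79 ± 0.35) were among the interstitial ones. Fibroblast markers fell in 4 of 11. Their list had 8 past adjusted over the list alone, median -1.11 (adjusted p = 5.6e-05, 0.353 with an estimated correlation). Cell cycle genes, all at low levels, fell in 5 of 31, with the replication helicase subunit Mcm5 at 0.573 ± 0.143 against 2.48 ± 0.497 CPM. Their list had 5 past adjusted over the list alone, median -0.68 (adjusted p = 0.00744, 0.328 with an estimated correlation). The count of genes was 1164 without CGD CD101neg replicate 2 and 1355 without WT CD101neg replicate 1. With library-size scaling only, the median of all genes shifted to -0.57 and 413 genes were higher and 3572 lower. The cell cycle list then did not pass (adjusted p = 0.105).

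CGD cells sorted as mature neutrophils after zymosan carried more transcripts of single genes such as Cxcl3, Irak3, Mt2 and Xbp1 than WT ones, and less Cd101. The macrophage marker C1qb was higher too, and macrophages or their RNA in this sort are a candidate source. Of the 12 lists that passed, 0 did so with an estimated correlation (lowest adjusted p = 0.186). The same question asked of CD101pos cells gave 878 genes, 459 higher and 419 lower in CGD. Of these, 292 were higher in CGD in CD101neg cells too (30.6 expected if independent), 163 were lower in both (26.1 expected) and 17 went opposite ways. The WT libraries of the 2 sorts pair by replicate number, so the comparisons are not independent. The largest increases were in the macrophage elastase Mmp12 (27.4 ± 14.5 against 1.49 ± 0.573 CPM, 4.19 ± 0.55), the non-classical MHC gene H2-M2 (4.09 ± 0.69) and Cxcl9 (4.07 ± 0.81). Beside Cybb, the maturation marker Cd101 was among the lowest (105 ± 7.96 against 403 ± 70.3 CPM, -1.95 ± 0.23, adjusted p = 0.000101).

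Cytokine and chemokine genes rose in 9 of 30 measured, with Cxcl3 at 3555 ± 464 against 466 ± 101 CPM (2.93 ± 0.30), Cxcl10 at 3.21 ± 0.57 and Il12a at 1.58 ± 0.27. The cytokine list had 13 past adjusted over the list alone, median 1.11 (adjusted p = 7.67e-12, adjusted p = 0.227 with an estimated correlation). IL-1 and inflammasome genes rose in 3 of 17, Irak3 at 1.14 ± 0.20 among them. The IL-1 list had 7 past adjusted over the list alone, median 0.84 (adjusted p = 9.49e-05, adjusted p = 0.186 with an estimated correlation). Interferon-stimulated genes rose in 2 of 37, Cxcl10 and Ifi47 (2.74 ± 0.53). The interferon list had 2 past adjusted over the list alone, median 0.55 (adjusted p = 0.00151, adjusted p = 0.835 with an estimated correlation). This list lost its call without CGD CD101pos replicate 3 (median -0.0068, adjusted p = 0.664) and WT CD101pos replicate 1 (median 0.44, adjusted p = 0.123). Antioxidant and NRF2 genes did not pass as a list (camera adjusted p = 0.0793), while 5 of 25 rose (5 up and 1 down adjusted over the list alone). They include the metallothioneins Mt2 (35.5 ± 4.15 against 2.51 ± 0.762 CPM, 3.81 ± 0.32) and Mt1 (2.05 ± 0.34) and the thioredoxin reductase Txnrd1 (1.31 ± 0.27). Unfolded protein response genes rose in 2 of 18, Xbp1 (913 ± 129 against 268 ± 6.76 CPM, 1.77 ± 0.20) and Manf (1.21 ± 0.23), and the list lost its call without CGD CD101pos replicate 3 (median 0.11, adjusted p = 0.061) and CGD CD101pos replicate 1 (median 0.22, adjusted p = 0.0747) and WT CD101pos replicate 2 (median 0.13, adjusted p = 0.0874). The unfolded protein response list had 3 up and 1 down adjusted over the list alone, median 0.22 (adjusted p = 0.0379, adjusted p = 0.619 with an estimated correlation).

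Mitochondrially encoded genes held 0.33% to 0.396% of the reads of CGD and 0.425% to 0.571% of those of WT CD101pos libraries. Alveolar macrophage markers rose in 5 of 15, the mannose receptor Mrc1 at 32.8 ± 15.7 against 9.83 ± 3.61 CPM (1.74 ± 0.35). The alveolar macrophage list had 9 up and 1 down adjusted over the list alone, median 1.13 (adjusted p = 7.25e-06, adjusted p = 0.227 with an estimated correlation). Monocyte and interstitial macrophage markers rose in 4 and fell in 1 of 14, C1qb at 102 ± 25.1 against 29.3 ± 17.2 CPM (1.80 ± 0.34) and F13a1 at 1.72 ± 0.31. The monocyte and interstitial macrophage list had 6 up and 1 down adjusted over the list alone, median 0.76 (adjusted p = 0.00497, adjusted p = 0.326 with an estimated correlation). The second list lost its call without CGD CD101pos replicate 3 (median 0.65, adjusted p = 0.0525) and WT CD101pos replicate 2 (median 0.75, adjusted p = 0.0549). B cell markers fell in 5 of 9, with Ighm at 41.4 ± 12.0 against 138 ± 9.08 CPM (-1.74 ± 0.23). The B cell list had 1 up and 6 down adjusted over the list alone, median -1.19 (adjusted p = 1.45e-05, adjusted p = 0.218 with an estimated correlation). Cell cycle genes stood higher with 0 of 31 past the threshold by edgeR. The cell cycle list had 0 past adjusted over the list alone, median 0.71 (adjusted p = 0.000745, adjusted p = 0.218 with an estimated correlation). NF-kB target genes rose in 3 of 25, a list call lost without WT CD101pos replicate 2 (median 0.29, adjusted p = 0.117). The NF-kB list had 3 past adjusted over the list alone, median 0.49 (adjusted p = 0.00295, adjusted p = 0.817 with an estimated correlation). Fungal and microbial recognition genes rose in 4 of 22, and the list lost its call without CGD CD101pos replicate 1 (median 0.29, adjusted p = 0.0599) and WT CD101pos replicate 1 (median 0.23, adjusted p = 0.123). The recognition list had 6 past adjusted over the list alone, median 0.33 (adjusted p = 0.00473, adjusted p = 0.429 with an estimated correlation). The count of genes fell to 578, 320, 339 and 443 without CGD CD101pos replicates 3 and 2 and WT CD101pos replicates 3 and 2. Library-size scaling only gave 308 higher and 490 lower.

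Without zymosan the genotypes differed in few single genes, and of the 15 lists that passed 0 did so with an estimated correlation (lowest adjusted p = 0.158). This comparison asks what differs at rest, in male mice of 12 weeks in both groups. Here 21 genes passed, 20 higher and 1, Cybb, lower in CGD, with 1147 genes at an unadjusted p under 0.05. Ear6, a ribonuclease of eosinophils and macrophages (1.55 ± 1.08 against 0.00516 ± 0.00894 CPM, 7.57 ± 0.85), and Cybb kept their call with each of the 6 libraries left out in turn. The largest other named increases were in melanoregulin (Mreg, 4.97 ± 0.91), Gpnmb (50.3 ± 44.4 against 2.92 ± 0.633 CPM, 4.11 ± 0.66) and the protease cathepsin K (Ctsk, 3.94 ± 0.56), and Spp1 was at 413 ± 407 against 46.2 ± 9.68 CPM (3.16 ± 0.59). Of the 20 higher genes, 9 were higher in CGD zymosan CD101pos cells (0.554 expected if independent) and 6 in CGD zymosan CD101neg cells (1.33 expected), where 1 was lower. Macrophage RNA in the CGD CD101pos sorts is an untested candidate source of these genes.

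Cytokine and chemokine genes rose in 1 of 30 and 28 had a fold change above 0. The cytokine list had 9 up and 1 down adjusted over the list alone, median 0.86 (adjusted p = 4.3e-12, adjusted p = 0.246 with an estimated correlation). The monocyte attractant Ccl2 passed (1.48 ± 0.28). None of 37 interferon-stimulated genes passed by edgeR and 35 were above 0. The interferon list had 2 past adjusted over the list alone, median 0.68 (adjusted p = 1.98e-09, adjusted p = 0.471 with an estimated correlation). Alveolar macrophage markers rose in 3 of 15, Ctsk, Marco (3.52) and Atp6v0d2 (3.47). Their list had 3 past adjusted over the list alone, median 0.53 (adjusted p = 1.39e-08, 0.185 with an estimated correlation). Of 14 monocyte and interstitial macrophage markers 0 passed by edgeR, a list call lost without WT naive replicate 1 (median 0.19, adjusted p = 0.0759). Their list had 0 past adjusted over the list alone, median 0.29 (adjusted p = 0.00555, 0.413 with an estimated correlation). Eosinophil markers rose in 1 of 5, Ear6, with a median that turned to -0.0076 when only these groups were fitted. The eosinophil list had 2 past adjusted over the list alone, median 0.52 (adjusted p = 0.000524, adjusted p = 0.158 with an estimated correlation). Secondary and tertiary granule genes, none of which passed, stood higher, but not without CGD naive replicate 3 (median -0.012, adjusted p = 0.181). The granule list had 2 past adjusted over the list alone, median 1.00 (adjusted p = 3.9e-05, adjusted p = 0.471 with an estimated correlation). Endothelial markers stood lower with none past the threshold. Their list had 0 past adjusted over the list alone, median -0.63 (adjusted p = 3.9e-05, 0.471 with an estimated correlation). The count of genes was 10, 4 and 64 without CGD naive replicates 3, 2 and 1 and 3, 2 and 2 without WT naive replicates 3, 2 and 1. Of Mreg, Gpnmb, Ctsk, Ccl2, Marco, Atp6v0d2 and Spp1, calls were lost without CGD naive replicates 2 and 3 (0.058 to 0.252, 0.0523 to 0.108), with the adjusted p in brackets. They were also lost without WT naive replicates 1, 2 and 3 (0.107 to 0.257, 0.134 to 0.296, 0.126 to 0.23).

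In WT lungs after zymosan, immature neutrophils carried more antioxidant and NRF2 transcripts than mature ones (8 of 25 rose, adjusted p = 0.0304 with an estimated correlation) and less Cd101. The comparison asks how the sorted subsets differ when the oxidase is intact, and 73 genes passed, 68 higher and 5 lower in CD101neg cells. Nqo1, which reduces quinones, was at 24.3 ± 13.2 against 1.99 ± 0.401 CPM (3.61 ± 0.43, adjusted p = 0.000925), and the peroxiredoxin Prdx1 at 418 ± 135 against 105 ± 38.4 CPM (2.0 ± 0.24, adjusted p = 0.000925). The largest increase was in Gdf15 (50.1 ± 51.6 against 2.86 ± 1.70 CPM, 4.13 ± 0.79). Cd101 fell from 403 ± 70.3 in CD101pos to 166 ± 16.1 CPM in CD101neg cells (-1.28 ± 0.23, adjusted p = 0.0148). Antioxidant and NRF2 genes rose in 8 of 25. The NRF2 list had 13 past adjusted over the list alone, median 0.63 (camera adjusted p = 5.64e-16, adjusted p = 0.0304 with an estimated correlation). Beside Nqo1 and Prdx1 they include haem oxygenase 1 (Hmox1, 642 ± 205 against 202 ± 22.9 CPM, 1.67 ± 0.25) and the autophagy receptor p62 (Sqstm1, 1.73 ± 0.31). Of mature neutrophil genes, 1 of 20 fell, Cd101, and 17 of 20 had a fold change below 0. The mature neutrophil list had 2 past adjusted over the list alone, median -0.31 (camera adjusted p = 0.000489, adjusted p = 0.696 with an estimated correlation).

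Interferon-stimulated genes (37 measured) and nuclear oxidative phosphorylation genes (55 measured) stood lower in CD101neg cells as lists with 0 members past the threshold by edgeR. The interferon list had 0 past adjusted over the list alone, median -0.40 (camera adjusted p = 0.000314, adjusted p = 0.94 with an estimated correlation). The oxidative phosphorylation list had 0 past adjusted over the list alone, median -0.18 (adjusted p = 0.00314, adjusted p = 0.94 with an estimated correlation). The second list did not pass without WT CD101neg replicate 3 (median -0.12, adjusted p = 0.0745) and WT CD101pos replicate 1 (median -0.16, adjusted p = 0.186). NF-kB target genes stood higher with 0 of 25 past it, a call lost without WT CD101neg replicate 3 (median 0.27, adjusted p = 0.294) and WT CD101pos replicate 2 (median 0.13, adjusted p = 0.61) and WT CD101neg replicate 1 (median 0.16, adjusted p = 0.259). The NF-kB list had 0 past adjusted over the list alone, median 0.34 (adjusted p = 0.0184, adjusted p = 0.94 with an estimated correlation). Cytokine genes did so with 0 of 30 past it, a call lost without WT CD101pos replicate 2 (median 0.17, adjusted p = 0.103). The cytokine list had 1 past adjusted over the list alone, median 0.43 (adjusted p = 0.000475, adjusted p = 0.94 with an estimated correlation). Markers of T and NK cells stood higher, with 0 of 15 past the threshold. The T and NK cell list had 3 past adjusted over the list alone, median 1.13 (adjusted p = 3.99e-05, adjusted p = 0.166 with an estimated correlation). B cell markers rose in 1 of 9, Igkc at 1.5 ± 0.33. The B cell list had 4 up and 1 down adjusted over the list alone, median 0.77 (adjusted p = 0.000883, adjusted p = 0.518 with an estimated correlation). Macrophage markers did not pass in either list (alveolar, median 0.19, camera adjusted p = 0.759, and monocyte and interstitial, median 0.28, camera adjusted p = 0.0668). Replicate numbers paired the WT subsets (correlations 0.487, 0.425 and 0.312 within numbers), though nothing states that a pair came from 1 animal. With the number as a block 748 genes passed, 365 higher and 383 lower. Without 1 library the count was 3, 16 and 17 (WT CD101pos replicates 3, 2 and 1) or 14, 400 and 40 (WT CD101neg replicates 3, 2 and 1). Nqo1 and Prdx1 held without each of the 6, but with only these groups in the fit no gene passed (adjusted p = 0.214 and 0.224 for these 2). Of Gdf15, Cd101, Hmox1, Sqstm1 and Igkc, calls were lost without WT CD101neg replicates 1, 2 and 3 (0.0549 to 0.0569, 0.0617, 0.136 to 0.204), with the adjusted p in brackets. Others were lost without WT CD101pos replicates 1, 2 and 3 (0.0739 to 0.141, 0.107 to 0.201, 0.0663 to 0.131). Library-size scaling only gave 48 higher and 1 lower, with the median of all genes at 0.13.

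In CGD lungs after zymosan, immature neutrophils carried fewer monocyte and interstitial macrophage marker (7 of 14 fell) and cell cycle transcripts (10 of 31 fell) than mature ones. Both lists passed also with an estimated correlation (adjusted p = 0.0202). RNA of other cells in the CD101pos sort is a candidate source of both, untested for the cell cycle list. The comparison gave 1218 genes, 542 higher and 676 lower in CD101neg than in CD101pos cells. The largest decreases were in the chemokine Ccl8 (0.473 ± 0.399 against 12.6 ± 0.819 CPM, -4.72 ± 0.65), the haemoglobin scavenger receptor Cd163 (0.743 ± 0.205 against 18.7 ± 9.39 CPM, -4.65 ± 0.55) and Fcrls (-4.47 ± 0.50). The largest increase was in Spp1 (8906 ± 3689 against 1354 ± 329 CPM, 2.72 ± 0.58), whose call was lost without CGD CD101pos replicate 2 (adjusted p = 0.0535). Cd101 was at 61.1 ± 18.4 against 105 ± 7.96 CPM (-0.77 ± 0.22, adjusted p = 0.0442), a call lost without CGD CD101pos replicate 3 (adjusted p = 0.126), CGD CD101neg replicate 3 (adjusted p = 0.183), CGD CD101pos replicate 2 (adjusted p = 0.118), CGD CD101neg replicate 1 (adjusted p = 0.0821). Between genotypes, 21 genes were higher in CD101neg cells in both (2.22 expected if independent), 4 were lower in both (0.204 expected) and 3 went opposite ways.

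Alveolar macrophage markers fell in 10 of 15. Their list had 10 past adjusted over the list alone, median -1.82 (adjusted p = 9.02e-12, 0.0719 with an estimated correlation). Monocyte and interstitial macrophage markers fell in 7 of 14. Their list had 7 past adjusted over the list alone, median -0.96 (adjusted p = 5.81e-11, 0.0202 with an estimated correlation). C1qa was at 2.58 ± 0.454 against 29.1 ± 9.93 CPM (-3.49 ± 0.34), C1qb at 10.7 ± 1.56 against 102 ± 25.1 CPM (-3.26 ± 0.37) and Mrc1 at 2.93 ± 0.821 against 32.8 ± 15.7 CPM (-3.48 ± 0.38). Cell cycle genes fell in 10 of 31, with Mcm5 at 0.573 ± 0.143 against 4.08 ± 2.21 CPM (-2.83 ± 0.40). The cell cycle list had 11 past adjusted over the list alone, median -1.36 (adjusted p = 6.3e-09, adjusted p = 0.0202 with an estimated correlation). NF-kB target genes rose in 8 of 25, led by Tnip1, an inhibitor of the pathway (439 ± 83.6 against 172 ± 36.5 CPM, 1.35 ± 0.28). The NF-kB list had 8 past adjusted over the list alone, median 0.46 (adjusted p = 2.46e-06, adjusted p = 0.487 with an estimated correlation). Cytokine and chemokine genes rose in 3 and fell in 2 of 30, with Csf3 (1.72 ± 0.31) and Il12a (1.46 ± 0.26) higher and the monocyte attractant Ccl7 lower (-2.69 ± 0.39). The cytokine list had 9 up and 5 down adjusted over the list alone, median 0.71 (adjusted p = 0.0183, adjusted p = 0.654 with an estimated correlation). The cytokine list lost its call without CGD CD101neg replicate 3 (median 0.52, adjusted p = 0.107) and CGD CD101pos replicate 1 (median 0.61, adjusted p = 0.0716). Antioxidant and NRF2 genes did not pass as a list here (median 0.082, camera adjusted p = 0.616), with 2 up and 4 down of 25 (4 up and 4 down adjusted over the list alone) and catalase among the lower ones (Cat, -1.18 ± 0.21).

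Epithelial markers fell in 5 of 15, Krt19 at 4.73 ± 1.16 against 19.9 ± 5.03 CPM (-2.07 ± 0.30). The epithelial list had 11 past adjusted over the list alone, median -1.45 (adjusted p = 5.01e-07, adjusted p = 0.284 with an estimated correlation). Dendritic cell markers fell in 3 of 7. The dendritic cell list had 4 past adjusted over the list alone, median -1.62 (adjusted p = 0.0119, adjusted p = 0.283 with an estimated correlation). The count of genes was 439 and 411 without CGD CD101pos replicates 3 and 2 and 367 and 321 without CGD CD101neg replicates 3 and 2. It was 2758 (1339 higher, 1419 lower) with the replicate number as a block, although the numbers do not pair the CGD subsets by the rule used. Library-size scaling only gave 82 higher and 1163 lower genes, with the median of all genes at -0.34.

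**Figure D4:**
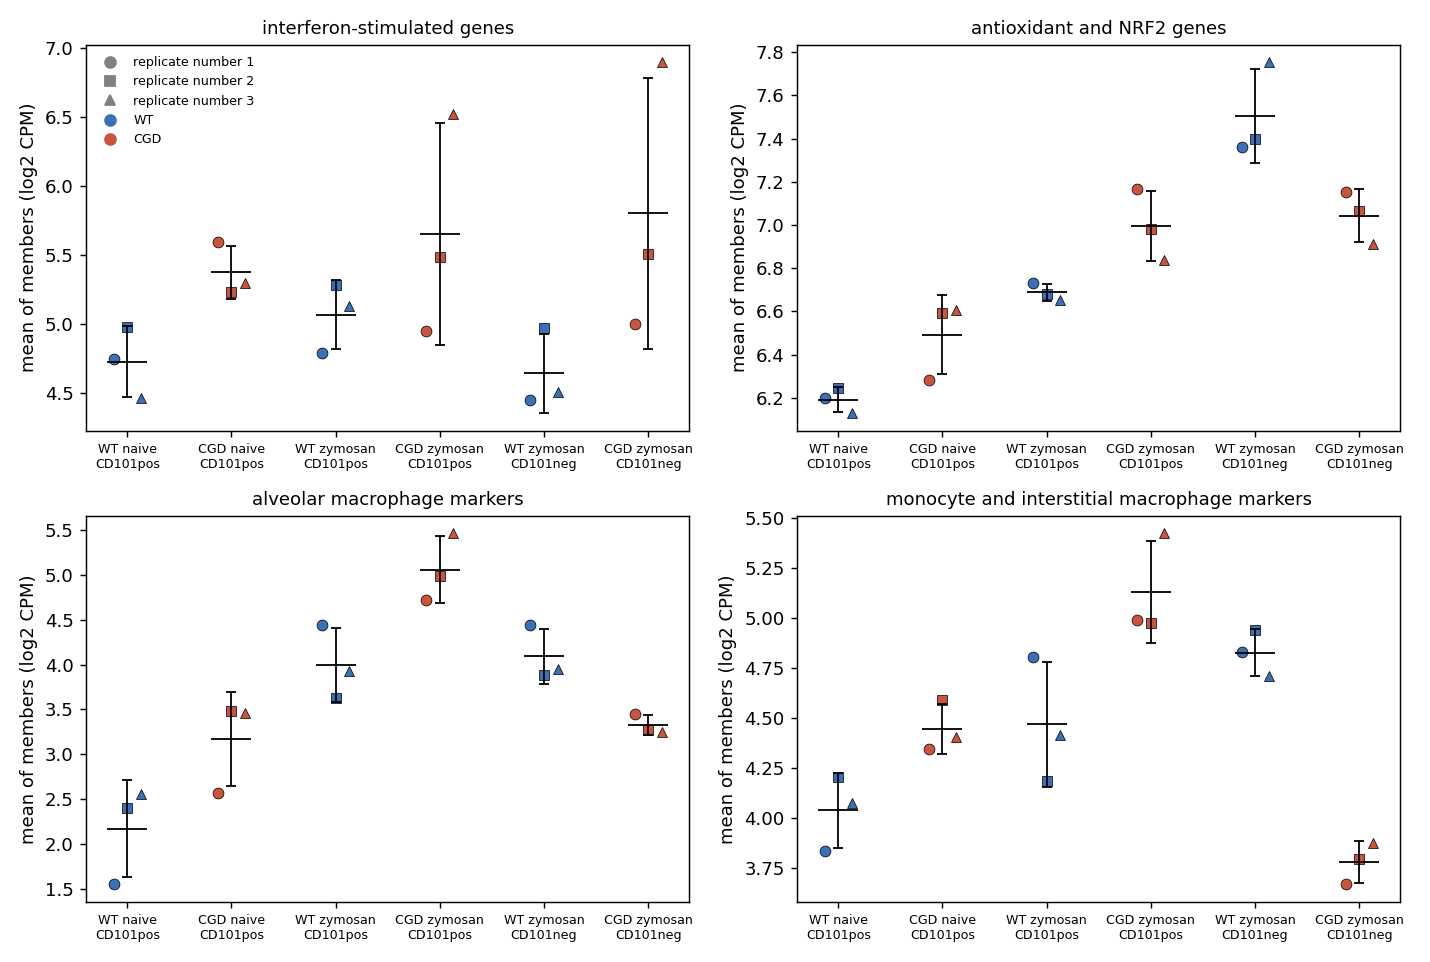
Each point is the mean log2 CPM of a list's members (y axes) in 1 library of the 6 groups (x axes), with symbols for replicate numbers, colours for genotype, horizontal lines for group means and bars for 1 SD of 3 libraries. Interferon-stimulated genes are highest in CGD replicate 3 (6.90 in CD101neg and 6.52 in CD101pos cells), antioxidant genes in WT CD101neg cells, and both kinds of macrophage marker in CGD zymosan CD101pos cells.

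Mature WT neutrophils carried more cytokine (16 of 30 rose), IL-1 (5 of 17) and primary granule transcripts (2 of 8) after zymosan. Eicosanoid genes (3 of 15) and alveolar macrophage and eosinophil markers rose too. These lists and B cell markers (6 of 9 fell) passed also with an estimated correlation (adjusted p of 0.00325 to 0.0439). RNA of other cells is an untested candidate source of the markers. The comparison asks what the challenge changes in CD101pos cells, but the groups also differ in sex and age. It gave 629 genes, 484 higher and 145 lower after zymosan. The acute-phase gene Saa3 was at 93.1 ± 29.2 against 0.33 ± 0.302 CPM (8.06 ± 0.70). The scavenger receptor Marco, also an alveolar macrophage marker, was at 14.2 ± 1.5 against 0.157 ± 0.143 CPM (6.49 ± 0.66). The largest decreases were in the Y-linked Eif2s3y (-10.45) and Ddx3y (-9.14), which follow the sexes of the groups, as does the sex-linked list with 1 up and 4 down of 5. The sex-linked list had 1 up and 4 down adjusted over the list alone, median -7.65 (adjusted p = 9.07e-39, adjusted p = 2.39e-06 with an estimated correlation).

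Cytokine and chemokine genes rose in 16 of 30. The cytokine list had 23 past adjusted over the list alone, median 2.12 (adjusted p = 2.18e-28, adjusted p = 0.023 with an estimated correlation). Il12a was at 10.5 ± 1.96 against 1.35 ± 0.369 CPM (2.97 ± 0.29), Cxcl3 at 466 ± 101 against 73.0 ± 16.2 CPM (2.67 ± 0.29) and Ccl2 at 2.41 ± 0.29. NF-kB target genes rose in 9 of 25, with the anti-apoptotic Cflar at 1.36 ± 0.23. The NF-kB list had 17 past adjusted over the list alone, median 0.80 (adjusted p = 6.18e-12, adjusted p = 0.118 with an estimated correlation). IL-1 and inflammasome genes rose in 5 of 17, with Il1a at 3.88 ± 0.73 and Mefv at 1.73 ± 0.23. The IL-1 list had 10 past adjusted over the list alone, median 0.77 (adjusted p = 6.82e-08, adjusted p = 0.0148 with an estimated correlation). Primary granule genes rose in 2 of 8, with the granule protease activator Ctsc at 1.68 ± 0.20. The primary granule list had 3 past adjusted over the list alone, median 0.76 (adjusted p = 0.00145, adjusted p = 0.023 with an estimated correlation). Those of secondary and tertiary granules rose in 1 of 19, Chil3 (2.68 ± 0.42), while Ltf (-1.42) and Camp (-1.66) were lower without passing. The granule list had 5 past adjusted over the list alone, median 1.11 (adjusted p = 0.00073, adjusted p = 0.42 with an estimated correlation). Leukotriene and prostanoid genes rose in 3 of 15, with the leukotriene B4 receptor Ltb4r1 at 1.49 ± 0.22. The eicosanoid list had 5 past adjusted over the list alone, median 0.63 (adjusted p = 0.00147, adjusted p = 0.023 with an estimated correlation). In the NADPH oxidase list 2 of 9 rose. It had 2 up and 1 down adjusted over the list alone, median 0.59 (adjusted p = 0.0217, 0.22 with an estimated correlation).

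Mitochondrially encoded genes fell in 3 of 13. Their list had 6 past adjusted over the list alone, median -0.59 (adjusted p = 1.89e-05, 0.22 with an estimated correlation). Interferon-stimulated genes rose in 2 of 37, a list whose median turned to -0.11 with library-size scaling only and whose call was lost without WT CD101pos replicate 2 (median 0.11, adjusted p = 0.21) and WT naive replicate 3 (median 0.19, adjusted p = 0.104). The interferon list had 3 past adjusted over the list alone, median 0.23 (adjusted p = 0.0189, adjusted p = 0.723 with an estimated correlation). B cell markers fell in 6 of 9, Cd79a at -2.21 ± 0.26. The B cell list had 8 past adjusted over the list alone, median -2.12 (adjusted p = 7.63e-18, adjusted p = 0.00325 with an estimated correlation). Markers of alveolar macrophages rose in 9 of 15. Their list had 10 past adjusted over the list alone, median 1.61 (adjusted p = 1.69e-12, 0.0294 with an estimated correlation). Those of eosinophils rose in 3 of 5. The eosinophil list had 3 past adjusted over the list alone, median 1.61 (adjusted p = 0.00073, adjusted p = 0.0439 with an estimated correlation). The count of genes was 360 without WT CD101pos replicate 3 and 263, 271 and 342 without WT naive replicates 3, 2 and 1. Library-size scaling only gave 264 higher and 617 lower, with the median of all genes at -0.33.

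Mature CGD neutrophils carried more cytokine (20 of 30 rose), IL-1 (10 of 17), eicosanoid and primary granule transcripts after zymosan, and fewer B cell transcripts (6 of 9 fell). Except for primary granules (0.0557), these lists passed also with an estimated correlation (adjusted p at most 0.0445). This comparison, with the same difference in sex and age, gave 2128 genes, 1182 higher and 946 lower. Both genotypes shared 333 higher genes (34.5 expected if independent) and 87 lower genes (8.28 expected). Apart from Xist (10.53), which follows the sexes, the largest increases were in Bcl2l15 (7.37 ± 0.82) and Saa3 (252 ± 76.9 against 2.61 ± 2.10 CPM, 6.60 ± 0.63). Below the Y-linked Eif2s3y (-9.89) and Ddx3y (-9.10), the largest decreases were in Scgb3a2 (-4.00 ± 0.82) and Igkc (-3.74 ± 0.36). Cd101 was at 105 ± 7.96 against 301 ± 72.2 CPM (-1.52 ± 0.23, adjusted p = 0.000189). Cybb, low in both groups, fell by 0.75 on the log2 scale (adjusted p = 0.00932), a call lost without CGD CD101pos replicate 2 (adjusted p = 0.0615).

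Cytokine and chemokine genes rose in 20 of 30. As a list, cytokine genes had 23 past adjusted over the list alone, median 2.12 (adjusted p = 3.87e-23, adjusted p = 0.0377 with an estimated correlation). Cxcl3 was at 3555 ± 464 against 174 ± 52.8 CPM (4.35 ± 0.32), Il12a at 3.35 ± 0.29 and Ccl7 at 3.48 ± 0.40. NF-kB target genes rose in 17 of 25, Nfkb1 at 1.42 ± 0.18 and the superoxide dismutase Sod2 at 345 ± 6.68 against 85.1 ± 18.9 CPM (2.02 ± 0.26) among them. As a list, NF-kB genes had 18 past adjusted over the list alone, median 0.92 (adjusted p = 4.12e-11, adjusted p = 0.172 with an estimated correlation). Genes of IL-1 and the inflammasome rose in 10 of 17. The IL-1 list had 12 past adjusted over the list alone, median 1.09 (adjusted p = 1.87e-09, adjusted p = 0.00492 with an estimated correlation). Unfolded protein response genes rose in 6 and fell in 1 of 18, with Xbp1 at 913 ± 129 against 176 ± 46.5 CPM (2.37 ± 0.20). The unfolded protein response list had 7 up and 1 down adjusted over the list alone, median 0.42 (adjusted p = 0.00177, adjusted p = 0.194 with an estimated correlation). NRF2 and other antioxidant genes rose in 6 and fell in 1 of 25. The NRF2 list had 7 up and 2 down adjusted over the list alone, median 0.16 (adjusted p = 0.00719, adjusted p = 0.372 with an estimated correlation). Its median was -0.11 with library-size scaling only, and the list lost its call without CGD naive replicate 1 (median -0.027, adjusted p = 0.0637). Mt2 (35.5 ± 4.15 against 1.15 ± 0.163 CPM, 4.94 ± 0.34) and the ferritin heavy chain Fth1 (1.63 ± 0.22) were the clearest.

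B cell markers fell in 6 of 9, Ighm at -2.80 ± 0.24. The B cell list had 7 past adjusted over the list alone, median -2.84 (adjusted p = 1.38e-16, adjusted p = 0.00492 with an estimated correlation). Alveolar macrophage markers rose in 8 of 15, Mrc1 at 3.19 ± 0.37. The alveolar macrophage list had 9 past adjusted over the list alone, median 2.33 (adjusted p = 2.88e-09, adjusted p = 0.0557 with an estimated correlation). Monocyte and interstitial macrophage markers rose in 5 and fell in 3 of 14, with C1qb at 102 ± 25.1 against 12.0 ± 3.39 CPM (3.08 ± 0.36), a list call lost without CGD CD101pos replicate 3 (median 0.11, adjusted p = 0.0691) and CGD naive replicate 3 (median 0.54, adjusted p = 0.0622) and CGD naive replicate 1 (median 0.12, adjusted p = 0.0906). The monocyte and interstitial macrophage list had 5 up and 5 down adjusted over the list alone, median 0.25 (adjusted p = 0.025, adjusted p = 0.372 with an estimated correlation). The count of genes was 1170 without CGD CD101pos replicate 2 and 1368 without CGD naive replicate 1. Scaling by library size alone gave 727 higher and 2021 lower, with the median of all genes at -0.24.

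The difference between the zymosan subsets was more negative in CGD than in WT for single genes such as Prdx1, C1qa and Mrc1. It was so for monocyte and interstitial macrophage markers (6 of 14) and cell cycle genes (1 of 31) as lists, also with an estimated correlation (adjusted p = 0.0129 and 0.0207). The interaction of genotype with subset tests whether the CD101neg against CD101pos difference is not the same in CGD and WT. It gave 141 genes, 30 with a more positive and 111 with a more negative difference in CGD. Prdx1 was at 418 ± 135 in CD101neg and 105 ± 38.4 in CD101pos cells of WT and 69.3 ± 4.32 and 129 ± 7.53 CPM in those of CGD, a difference of -2.90 ± 0.33 (adjusted p = 0.000968). C1qa was at 11.1 ± 3.87 in CD101neg and 9.60 ± 3.85 in CD101pos cells of WT and 2.58 ± 0.454 and 29.1 ± 9.93 CPM in those of CGD (-3.70 ± 0.45, adjusted p = 0.001). Ccl8 (-4.99 ± 0.83), Cd163 (-4.94 ± 0.71), Mrc1 (-3.44 ± 0.50) and Cat (-1.77 ± 0.30) likewise had a more negative subset difference in CGD. Il12a (1.69 ± 0.37) and Irak3 (1.35 ± 0.28) had a more positive one.

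Monocyte and interstitial macrophage markers had a more negative difference in 6 of 14. Their list had 9 past adjusted over the list alone, median -1.53 (adjusted p = 1.78e-13, 0.0129 with an estimated correlation). Alveolar macrophage markers did so in 4 of 15. Their list had 10 past adjusted over the list alone, median -2.06 (adjusted p = 4.11e-11, 0.0843 with an estimated correlation). Cell cycle genes did so in 1 of 31. The cell cycle list had 8 past adjusted over the list alone, median -1.52 (adjusted p = 2.03e-08, adjusted p = 0.0207 with an estimated correlation). NRF2 and other antioxidant genes did so in 3 of 25, Prdx1, Cat and Nqo1. The NRF2 list had 1 up and 9 down adjusted over the list alone, median -0.77 (adjusted p = 6.96e-06, adjusted p = 0.138 with an estimated correlation). Without 1 library the count was 43, 82, 59 and 47 (CGD CD101pos replicates 3 and 2 and CD101neg replicates 3 and 2). It was 45, 59 and 497 (WT CD101pos replicates 3, 2 and 1) or 85, 234 and 51 (WT CD101neg replicates 3, 2 and 1). Of Il12a, Irak3 and Nqo1, calls were lost without CGD CD101neg replicates 2 and 3 (0.0524 to 0.0787, 0.0575 to 0.0857) or CGD CD101pos replicates 1, 2 and 3 (0.0557 to 0.0744, 0.0594 to 0.0603, 0.0636 to 0.118), with the adjusted p in brackets. In WT they were lost without WT CD101neg replicates 1 and 3 (0.0554 to 0.102, 0.0532 to 0.0823) or WT CD101pos replicates 2 and 3 (0.0555 to 0.102, 0.0981 to 0.111). Scaling by library size alone gave 1 gene with a more positive and 163 with a more negative difference and put the median of all genes at -0.45. The replicate number as a block gave 431 with a more positive and 617 with a more negative one.

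Mt2, Cd38, Ecm1 and Rhoh changed more positively after zymosan in mature CGD than in mature WT neutrophils, and Cd101 more negatively. The interaction of genotype with zymosan asks whether the challenge acts alike in both genotypes, and an effect of sex or age that is equal in both cancels in it. Here 53 genes passed, 27 with a more positive and 26 with a more negative change in CGD. From naive to zymosan, the metallothionein Mt2 went from 0.83 ± 0.365 to 2.51 ± 0.762 CPM in WT and from 1.15 ± 0.163 to 35.5 ± 4.15 CPM in CGD (3.36 ± 0.44, adjusted p = 0.00205). The NAD-consuming ectoenzyme Cd38 went from 11.1 ± 1.5 to 20.1 ± 5.74 CPM in WT and from 9.59 ± 2.09 to 136 ± 26.2 CPM in CGD (2.97 ± 0.41). The extracellular matrix protein Ecm1 (2.54 ± 0.30) and the small GTPase Rhoh (2.43 ± 0.29) also had a more positive change in CGD. These 4 kept their call with each of the 12 libraries left out in turn. The largest estimate, of Cd163 (4.05 ± 0.71), did not. Cd101 went from 375 ± 60.05 to 403 ± 70.3 CPM in WT and from 301 ± 72.2 to 105 ± 7.96 CPM in CGD (-1.63 ± 0.32, adjusted p = 0.0349).

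Of the lists, mitochondrially encoded genes and epithelial markers had a more positive change in CGD with 0 members past the threshold by edgeR. The mitochondrially encoded list had 1 past adjusted over the list alone, median 0.48 (adjusted p = 0.00528, adjusted p = 0.952 with an estimated correlation). The epithelial list had 0 past adjusted over the list alone, median 0.75 (adjusted p = 0.00528, adjusted p = 0.952 with an estimated correlation). Eosinophil markers had a more negative one with 0 members past it. The eosinophil list had 2 past adjusted over the list alone, median -3.20 (adjusted p = 0.0165, adjusted p = 0.813 with an estimated correlation). B cell markers had it in 1 of 9, Ighm at -1.55 ± 0.32. As a list, B cell markers had 3 past adjusted over the list alone, median -0.64 (adjusted p = 0.0461, adjusted p = 0.952 with an estimated correlation). Without 1 library the count was 24, 5 and 23 (CGD CD101pos replicates 3, 2 and 1), 8 and 22 (WT CD101pos replicates 3 and 2). It was 24, 16 and 34 (CGD naive replicates 3, 2 and 1) or 10, 5 and 17 (WT naive replicates 3, 2 and 1). Of Cd163, Cd101 and Ighm, calls were lost without CGD CD101pos replicates 1, 2 and 3 (0.0731, 0.0873 to 0.165, 0.0541 to 0.0999) or CGD naive replicates 1, 2 and 3 (0.0525 to 0.112, 0.0536 to 0.0727, 0.0536), with the adjusted p in brackets. In WT they were lost without WT CD101pos replicates 1, 2 and 3 (0.0551, 0.0585 to 0.0652, 0.08 to 0.129) or WT naive replicates 1, 2 and 3 (0.0528 to 0.0898, 0.0604 to 0.127, 0.0667 to 0.139). The list of mitochondrially encoded genes lost its call without CGD naive replicate 1 (median 0.33, adjusted p = 0.0855), that of epithelial markers without WT CD101pos replicate 3 (median 0.51, adjusted p = 0.0702). That of eosinophil markers lost it without WT CD101pos replicate 3 (median -1.03, adjusted p = 0.0619) and CGD naive replicate 2 (median -2.87, adjusted p = 0.0545). That of B cell markers lost it without CGD CD101pos replicate 2 (median -0.78, adjusted p = 0.0761) and WT CD101pos replicate 3 (median -0.58, adjusted p = 0.0702) and WT CD101pos replicate 1 (median -0.62, adjusted p = 0.127) and CGD naive replicate 2 (median -0.58, adjusted p = 0.118) and WT naive replicate 2 (median -0.73, adjusted p = 0.0872) and WT naive replicate 1 (median -0.56, adjusted p = 0.141). Scaling by library size alone gave 9 genes with a more positive and 4 with a more negative change.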

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

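The tests of other cell types, of macrophage RNA, of scaling and of a single CGD library were chosen only after the result was seen, while the counts of splits were written before. Of the 17 unlisted macrophage genes, values of Cbr2 and Trem2 had been seen before the genes were chosen. An effect that differed between genotypes, by the interaction with subset in edgeR, was found for 141 genes. A more negative CD101neg against CD101pos difference in CGD was found for Ccl8 (-4.99), Cd163 (-4.94), C1qa (-3.70), Mrc1 (-3.44), Prdx1 (-2.90), Nqo1 (-2.94), Mcm5 (-2.86) and Cat (-1.77). A more positive one was found for Plekhn1 (2.49), Slc44a1 (2.15), Il12a (1.69), Hspa4l (1.64) and Irak3 (1.35). Of Nqo1, Mcm5, Plekhn1, Il12a, Hspa4l, Irak3 and Slc44a1, calls were lost without CGD CD101neg replicates 2 and 3 (0.0524 to 0.0787, 0.0534 to 0.0874) or CGD CD101pos replicates 1, 2 and 3 (0.0557 to 0.0744, 0.0594 to 0.0902, 0.0584 to 0.118), with the adjusted p in brackets. In WT they were lost without WT CD101neg replicates 1 and 3 (0.0554 to 0.102, 0.0532 to 0.0823) or WT CD101pos replicates 2 and 3 (0.0555 to 0.102, 0.0596 to 0.119). By camera, the list medians of this interaction were -1.52 for cell cycle, -0.77 for antioxidant and NRF2, -0.58 for mitochondrially encoded and -0.31 for ribosomal protein genes. They were 0.56 for interferon-stimulated, 0.56 for glycolysis and hypoxia, 0.37 for microbial recognition, 0.35 for NF-kB target, 0.30 for IL-1 and 0.30 for mature neutrophil genes. With library-size scaling only, the last 4 turned to -0.066, -0.10, -0.17 and -0.11. Marker medians were -2.06 for alveolar macrophages, -1.53 for monocytes and interstitial macrophages, -1.50 for T and NK cells, -1.41 for B cells, -1.40 for epithelial cells, -0.89 for fibroblasts and -0.26 for dendritic cells. With an estimated correlation, cell cycle (adjusted p = 0.0207) and monocyte and interstitial macrophage lists (0.0129) alone still passed, and the other 15 had an adjusted p of at least 0.0843.

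List calls of this interaction that 1 library carried were these. The mature neutrophil list lost its call without CGD CD101pos replicate 3 (median 0.30, adjusted p = 0.088) and WT CD101neg replicate 1 (median 0.26, adjusted p = 0.0727). The IL-1 list did so without WT CD101pos replicate 3 (median 0.14, adjusted p = 0.0985) and WT CD101neg replicate 2 (median 0.31, adjusted p = 0.0617). The NF-kB list did so without CGD CD101neg replicate 3 (median 0.29, adjusted p = 0.0616) and WT CD101pos replicate 3 (median 0.18, adjusted p = 0.151) and WT CD101neg replicate 2 (median 0.086, adjusted p = 0.52) and WT CD101pos replicate 1 (median 0.23, adjusted p = 0.0816). The interferon list did so without CGD CD101neg replicate 3 (median -0.023, adjusted p = 0.565). The mitochondrially encoded list did so without CGD CD101neg replicate 2 (median -0.45, adjusted p = 0.0752) and CGD CD101pos replicate 1 (median -0.40, adjusted p = 0.0867) and WT CD101pos replicate 3 (median -0.49, adjusted p = 0.0866) and WT CD101neg replicate 2 (median -0.56, adjusted p = 0.0616). The ribosomal protein list did so without CGD CD101pos replicate 1 (median -0.15, adjusted p = 0.0808). The recognition list did so without CGD CD101pos replicate 3 (median 0.26, adjusted p = 0.123) and WT CD101pos replicate 3 (median 0.30, adjusted p = 0.0866).

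The interaction with zymosan differed between genotypes for 53 genes. The change in CD101pos cells was more positive in CGD for Cd163 (4.05), Mt2 (3.36), Cd38 (2.97), Adm (2.84), Ecm1 (2.54), Rhoh (2.43) and Xbp1 (1.52). It was more negative for E2f2 (-1.85), Slc25a33 (-1.84), Tlr5 (-1.74), Mbp (-1.65) and Cd101 (-1.63). Mt2, Cd38, Ecm1 and Rhoh kept their call with each of the 12 libraries left out in turn. Of the other 8, calls were lost without CGD CD101pos replicates 1, 2 and 3 (0.0647 to 0.0957, 0.0873 to 0.165, 0.0541 to 0.104) or CGD naive replicates 1, 2 and 3 (0.0525 to 0.111, 0.0536 to 0.0816, 0.0536 to 0.101), with the adjusted p in brackets. In WT they were lost without WT CD101pos replicates 1, 2 and 3 (0.0551, 0.0537 to 0.103, 0.08 to 0.139) or WT naive replicates 1, 2 and 3 (0.0528 to 0.154, 0.0604 to 0.137, 0.0665 to 0.154). List medians were 0.48 for mitochondrially encoded genes, 0.75 for epithelial, -0.64 for B cell and -3.20 for eosinophil markers. None of these 4 lists passed with an estimated correlation (adjusted p of at least 0.813). The mitochondrially encoded list lost its call without CGD naive replicate 1 (median 0.33, adjusted p = 0.0855), and the epithelial list without WT CD101pos replicate 3 (median 0.51, adjusted p = 0.0702). The eosinophil list lost it without WT CD101pos replicate 3 (median -1.03, adjusted p = 0.0619) and CGD naive replicate 2 (median -2.87, adjusted p = 0.0545). The B cell list lost it without CGD CD101pos replicate 2 (median -0.78, adjusted p = 0.0761) and WT CD101pos replicate 3 (median -0.58, adjusted p = 0.0702) and WT CD101pos replicate 1 (median -0.62, adjusted p = 0.127) and CGD naive replicate 2 (median -0.58, adjusted p = 0.118) and WT naive replicate 2 (median -0.73, adjusted p = 0.0872) and WT naive replicate 1 (median -0.56, adjusted p = 0.141).

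Macrophage marker transcripts were lower in the CD101neg than in the CD101pos sort of CGD lungs after zymosan. More of all other cell types in the CD101pos sort would move their markers alike. The 29 macrophage markers had a median of -1.71 and the 88 markers of the 10 other cell types one of -0.56. The difference, -1.15, leaves this open, as its permutation (p = 8e-05) shuffled genes, not samples. A first form on 42 markers of 4 of these types gave -1.20. Epithelial (-1.45) and dendritic cell markers (-1.62) fell nearly as far, so a larger share of these cells too stays open. Macrophages or their RNA in that sort are a candidate explanation, since 17 macrophage genes outside the lists had a median of -1.51, 17 of them below 0 and 12 past the threshold, against 0.071 in WT. Levels in CGD CD101pos cells were 102 ± 25.1 CPM for C1qb, 32.8 ± 15.7 for Mrc1 and 29.1 ± 9.93 for C1qa, and the gate on CD11b and Ly6G should remove macrophages. A change of these genes inside neutrophils of the genotype and the source of the lower cell cycle transcripts stay open, as untested.

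Antioxidant and NRF2 genes were higher in the CD101neg than in the CD101pos sort of WT lungs after zymosan. Macrophage RNA would need its markers to move as far. These had a median of 0.23 (upper quartile 0.38). The 8 antioxidant genes past the threshold had one of 1.65 but were picked for passing, so macrophage RNA stays open. The list's adjusted p cannot test scaling, which moves genes nearly alike. It was 4.98e-17 with library-size scaling only, 5.64e-16 with TMM and 1.45e-21 to 0.0304 over its alternatives. A response of immature cells to their own oxidants stays open, and the interaction with subset (-2.90 for Prdx1, list median -0.77) bears on it without separating it from other effects of the genotype.

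Interferon-stimulated genes were higher in CGD than in WT CD101neg cells after zymosan. A single CGD library carried much of this, since 5 of the 16 genes past the threshold kept their call without CGD CD101neg replicate 3, while 16 and 15 did without replicates 1 and 2. Without it the list median went from 1.08 to 0.49 (adjusted p = 5.16e-05). With library-size scaling only the list median was still 0.63 (adjusted p = 1.73e-12, 7.5e-18 to 0.4 over its alternatives), but this p hardly tests scaling. There 8 of the 16 genes kept their call. A first form of the test asked whether at least 8 of the 16 would, and was replaced by the list test after just meeting that bound.

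The splits of the 6 libraries of a pairwise comparison number 10, the real one included, too few for a share under 0.05. In 1 of the 10, the real one, as many genes passed for each pairwise comparison except the WT subsets. The real count and the highest other were 2139 and 0 for the genotypes in CD101neg cells, 878 and 0 in CD101pos cells, 21 and 1 in naive cells, 1218 and 0 for the CGD subsets, and 629 and 0 and 2128 and 0 for zymosan in WT and CGD. For the WT subsets 2 of 10 gave as many, the real one 73 and the highest other 1352. That split set CD101neg replicates 1 and 3 and CD101pos replicate 1 against CD101neg replicate 2 and CD101pos replicates 2 and 3, and its count, many times the real one, points to a structure of the samples. Among the 4 splits with 1 library of each replicate number on each side the highest other was 0. For the interaction with subset 3 of 40 draws gave as many, the real one 141 and the highest other 2578, in which all 3 genotype labels of the CD101neg arm were exchanged. For the interaction with zymosan 3 of 40 gave as many, with 53 and 287. By these shares chance is not excluded for either interaction. Each other draw that gave as many kept or exchanged all labels of 1 arm, and holds its genotype difference. Draws with 1 or 2 labels exchanged in both arms mix genotypes in every group, so their 0 by edgeR decides nothing.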

How the results depend on the processing

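Scaling by library size only was chosen only after the result was seen, and all other alternatives were fixed before. Of 520 named gene results and 123 list results past the threshold, 0 of the gene results changed direction under any alternative run. Of 6584 gene values 5319 stayed past the threshold and 1265 did not, 968 of them with 1 library left out. DESeq2 kept all 520, RLE size factors 512, the block 501, no filter 459, library-size scaling 416 and only the groups compared 411 of 516. Of the 123 list results an estimated correlation kept 20, fry 64, library-size scaling 109 and leaving out 1 library 783 of 864 values. List medians changed sign in 12 of 1725 values. The cause of these changes was not tested, beyond fewer libraries where some are left out.

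The 12 medians were these, and the cause was not tested. With library-size scaling only, the interferon list for zymosan in WT was at -0.11, the antioxidant list for zymosan in CGD at -0.11, and in the interaction with subset the mature neutrophil, IL-1, NF-kB and recognition lists at -0.11, -0.17, -0.10 and -0.066. With only the groups compared, eosinophil markers of naive cells were at -0.0076. With each library left out in turn, medians ranged from -0.0068 to 0.86 for the interferon list between genotypes in CD101pos cells (lowest without CGD CD101pos replicate 3), from -0.012 to 1.34 for the granule list and from -0.045 to 0.30 for the NF-kB list in naive cells (lowest without CGD naive replicates 3 and 2). They ranged from -0.027 to 0.43 for the antioxidant list for zymosan in CGD (lowest without CGD naive replicate 1) and from -0.023 to 1.12 for the interferon list in the interaction with subset (lowest without CGD CD101neg replicate 3).

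The counts of genes moved over 1.5 times in these cases, and the cause was not tested. With library-size scaling only the genotype comparison of CD101neg cells gave 3985, that of naive cells 9 and the interaction with zymosan 13. With only the groups compared, the genotype comparisons of CD101neg, CD101pos and naive cells gave 1062, 572 and 6, the interaction with subset 62 and the WT subsets 0 by edgeR, where the fit of all libraries gave 73 and 1698 at an unadjusted p under 0.05. DESeq2 gave 1407 and 110 for the genotypes in CD101pos and naive cells, 305 and 2066 for the WT and CGD subsets, 1213 for zymosan in WT, and 589 and 261 for the interactions with subset and zymosan. Without a filter the WT subsets gave 140 and these interactions 327 and 119. With RLE size factors no count moved so far.

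With the replicate number as a block the WT subsets gave 748, the CGD subsets 2758 and the interaction with subset 1048. The numbers pair the WT subsets (correlations 0.487, 0.425 and 0.312), and in CGD (0.236, 0.0245 and 0.26) they do not by the rule used, although 6 of 6 libraries fit best with their own number.

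With each library left out in turn the counts ranged from 1164 to 1938 and 320 to 1125 for the genotypes in CD101neg and CD101pos cells, 2 to 64 in naive cells, 3 to 400 and 321 to 1185 for the WT and CGD subsets, 263 to 560 and 1170 to 1891 for zymosan in WT and CGD, and 43 to 497 and 5 to 54 for the interactions with subset and zymosan. Of the 520 gene results 294 kept their call with every library left out. Simulated 2-fold changes were recovered in 24% for the genotypes in CD101neg cells and 5% for the interaction with subset.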

Other observations

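The test of genes beside Cybb was chosen only after the result was seen. Genes near a disrupted gene may keep the sequence of the strain it was made in, and differ between genotypes for that reason. Of the 20 tested genes nearest to Cybb 5 passed in zymosan CD101neg cells (2.58 expected by chance, exact hypergeometric p = 0.105), 2 in zymosan CD101pos and 0 in naive cells by edgeR, where 1147 genes had an unadjusted p under 0.05. The count leaves this open.

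The secondary granule gene Ltf varied between libraries of a group. It was at 93.9, 101 and 963 CPM in CGD naive replicates 1, 2 and 3, at 83.1, 1556 and 249.9 in WT CD101neg and at 706, 285 and 178 in CGD CD101neg cells. WT CD101pos libraries had 30.3, 19.1 and 12.2 CPM after zymosan.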
